A study of Homo sapiens with 9 samples.

How the data were processed

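Messenger RNA levels were measured by RNA-seq in CA46, an established human B cell line that carries a Burkitt lymphoma translocation of MYC. The cells were infected for 48 h with a virus carrying either a non-targeting shRNA or an shRNA against MYC, and were kept in PBS or in 10 mM dimethyl succinate (DMS, a membrane-permeable ester of succinate) for the last 20 h. The labels name 4 RNA-seq libraries, 1 for each combination of virus and medium, and the group of each library was taken from its own treatment label. The same series also holds 4 ChIP-seq samples of trimethylated lysine on histone H3 with a fly chromatin spike-in and 1 input sample, which were not analysed here. Total RNA was extracted with TRIZOL and libraries were made with a NEBNext Ultra RNA kit, per the labels' protocols.

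Per the submitters' processing notes, the software comprised bcl2fastq, fastp, Bowtie2 2.2.6, MACS 1.4.2, TopHat2 2.1.0 and Cuffdiff 2.2.1, and the builds were those of human (hg19) and fly (dm6). The notes give no role or order, and the gene annotation and the strand setting are not given in the sources used here. Each deposited table held 1 column of FPKM (fragments per kilobase of gene model, scaled to library depth) for 31016 rows, although its title speaks of read counts. The unit was read from the values: they were fractional, the column names were those that Cuffdiff writes, and the lowest values of a gene came in whole steps that shrank with the length of the gene. The column name differed for 1 of the 4 libraries, and neither the scaling between libraries in the deposited FPKM nor whether Cuffdiff was run on all libraries together is stated.

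The sequencing depth was not given. The size of the steps in 19 to 33 low genes per library, of 600 to 3000 bp, implied 22.9 fragments per kilobase for each FPKM for the control virus in PBS, 25.7 for the control virus in DMS, 24.0 for the knockdown in PBS and 24.8 for the knockdown in DMS. These are estimates from the step size, and no counting interval was computed from them. Gene length was the span of the locus. The median was taken inside a fixed window of low values, which itself bounds the estimate, so differences between libraries are not resolved. Rows with no gene name (3919 rows) were left out of scaling and tests. They took 15.7% and 14.3% of the summed FPKM in the control libraries in PBS and DMS, and 25.2% and 22.4% in the knockdown libraries. Small RNA genes (2051 symbols) were also left out, because FPKM of such short genes is unstable. FPKM was summed over the rows of a symbol (690 symbols had several rows), and 503 rows that join several overlapping genes were kept as 1 feature each. In 30 rows the gene name had been turned into a date, and these were counted but never named. Gene biotypes and older symbols came from a RefSeq table of GRCh38.p14, which matched 21628 of 23182 symbols; no coordinates were taken from it. Coordinates are those of the deposited tables, on hg19, counted from 1.

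Libraries were rescaled by a trimmed mean of log2 ratios to the mean library, with 30% of ratios and 5% of levels trimmed at each end. The factors were 1.06, 1.04, 0.944 and 0.963 in the order above. FPKM values given for genes are rescaled unless called deposited. Genes with a mean of at least 1 FPKM over the 4 libraries were kept (11181 genes). Log2 ratios were taken on log2(FPKM + 1), which understates the change of low genes. A gene counted as higher or lower in a comparison of 2 libraries when this ratio was at least 1 in size, a 2-fold difference.

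With 1 library per group, a comparison of 2 libraries had no replicate check and no p-value. The spread between libraries could be estimated only by pooling: limma 3.58.1 with an intensity trend (R 4.3.3) was fitted to log2(FPKM + 1) with virus and medium as additive terms, which leaves 1 residual degree of freedom per gene and an estimated 5.07 prior degrees of freedom. Any difference in DMS response between the viruses enters its residual. P-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The labels do not say that the libraries came from separate cultures, so the limma p-values measure only the spread among these 4 libraries. In data simulated for the knockdown over both media on 11181 genes, the fit recovered 98.5% of 67 genes changed by 1 log2 unit, and called 0.501% of unchanged genes. Of 254 calls in these data, with 200 changed genes, 55 (21.7%) were of unchanged genes, so the adjusted threshold was not held there.

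The count-based tests planned before the data were examined, and the binomial splitting and exact count intervals planned with them, could not be run because the values are not counts. The limma fit, which was not among those planned tests, took their place. Before the data were examined 40 gene lists were fixed. The median log2 ratio of a list was placed among 10000 random lists of the same size and matched in 20 bins of mean expression, which describes these libraries only. Over the additive model the lists were tested with camera at a preset correlation of 0.01 and again with the correlation estimated from the residuals. At the preset correlation the p-value takes genes as nearly independent, so it does not measure the spread among libraries. With an estimated correlation the test has 1 degree of freedom and can hardly call a list. The lists of mitochondrially encoded genes and of erythroid markers had no member past the filter, and 38 lists were tested.

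Genes were named by a rule fixed before the data were examined: every member of the study axis, with MYC first; the 6 highest and the 6 lowest log2 ratios of each comparison among genes with a mean of at least 5 FPKM; up to 4 members of each list with the largest log2 ratio; the 10 genes that rose and the 10 that fell most in the additive fit, past the threshold and in the same direction in both pairs; and the 6 genes in each direction for the difference between DMS responses and for the return toward control. A named gene may be given again in other comparisons, and some genes that the rule names are not reported here. Members of multigene families (HLA and histone genes) and genes that overlap others may share fragments, and their values are uncertain to that extent.

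The alternatives were scaling by the median ratio, values as deposited, no filter, a minimum mean of 5 FPKM, a fit without the second term, each library left out, and an estimated correlation for the lists. A pseudocount of 0.25, small RNA genes kept, 1 row per symbol, and the values as deposited for the list medians and the return toward control were added after the data were seen. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used.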

Results

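The study followed how MYC controls the gene programme of CA46 cells and whether succinate, the substrate of succinate dehydrogenase (SDH), can raise promoter H3K4 trimethylation and expression once MYC is depleted. The part analysed here is the RNA-seq arm, a crossed design of virus (non-targeting control or Myc shRNA) and medium (PBS or 10 mM dimethyl succinate, DMS) with 1 library in each of the 4 groups. Depth was not given. The step size of low values, read inside a fixed window that bounds the estimate, implied 22.9 to 25.7 fragments per kilobase for each FPKM. All values of single libraries below stand without replicates, so differences between libraries are given as higher or lower, and only the pooled limma fit carries a test.

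MYC itself was measured first, since it is the target of the shRNA. In the control cells MYC (chromosome 8, 128748315 to 128753680, hg19) stood at 1856 FPKM in PBS and 1649 FPKM in DMS. It was 17.2 FPKM in the knockdown cells in PBS, 0.928% of the control library in the same medium. In the knockdown cells in DMS it was 624 FPKM, which is 37.9% of the control library in DMS and 36.3-fold above the knockdown cells in PBS. The deposited values before rescaling were 1964, 1713, 16.3 and 601 FPKM in the same order. The knockdown library in DMS therefore held far more MYC mRNA than the knockdown library in PBS, which bears on every gene group compared with it below.

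The other members of the MYC, SKP2, SIRT3 and SDH axis that the study addresses mostly lay below control in the knockdown. With MYC counted, 5 of 11 axis members were at least 2-fold lower in PBS, and 1 of 11 in DMS, MYC itself. SKP2, the substrate receptor of a ubiquitin ligase, was 32.9 and 33.9 FPKM in the control cells in PBS and DMS, 10.99 FPKM in the knockdown in PBS and 18.5 FPKM in the knockdown in DMS. SIRT3, a mitochondrial deacetylase, varied less, at 9.66, 10.9, 7.33 and 8.69 FPKM in the same order. The catalytic subunits followed the SKP2 order: SDHA was 141, 149, 61.2 and 84.6 FPKM, and SDHB was 124, 127, 51.5 and 80.8 FPKM. The membrane subunits differed less, with SDHC at 46.5, 50.6, 37.2 and 40.7 FPKM and SDHD at 93.5, 81.4, 52.1 and 60.4 FPKM. Among assembly factors SDHAF3 showed the widest range (47.5, 45.1, 12.2 and 26.7 FPKM), while SDHAF1 was 37.7, 39.3, 21.8 and 29.2 FPKM. SDHAF2 was higher in the knockdown in PBS (60.7 FPKM) than in the other libraries (43.3, 44.3 and 48.0 FPKM), and SDHAF4 lay between 12.9 and 17.0 FPKM in every library.

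**Figure D1:**
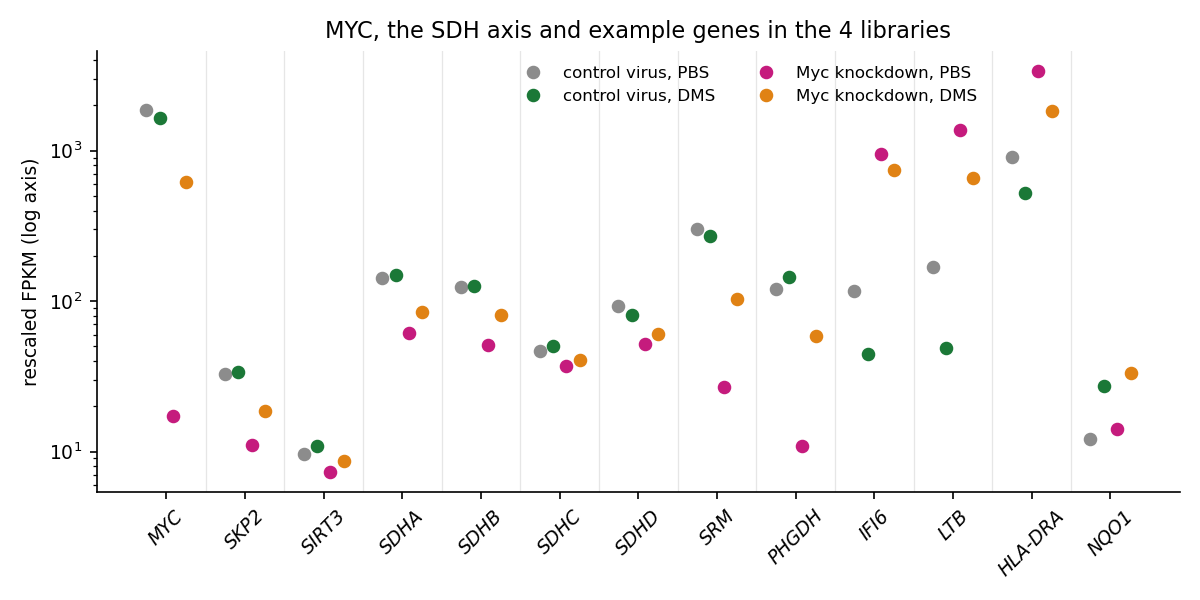
Rescaled FPKM on a log axis for MYC, members of the SDH axis and example genes, 1 point per library and no error bars because each group has 1 library. MYC was 1856 and 1649 FPKM in the control libraries, 17.2 FPKM in the knockdown in PBS and 624 FPKM in the knockdown in DMS.

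The first comparison asked what depletion of MYC did in PBS. Genes of growth and biosynthesis were lower in the knockdown and genes of the interferon response and of antigen presentation were higher: 1845 of 11181 genes were at least 2-fold lower and 1663 at least 2-fold higher. Among 57 MYC-activated targets 54 were lower by this rule and none higher, with a median log2 ratio of -2.17 that lay below all 10000 matched random lists. Examples were SRM, the spermidine synthase (302 FPKM in control, 26.8 in knockdown), the mitochondrial chaperone HSPD1 (551 and 54.7), NOP16 (171 and 17.4) and the purine enzyme PAICS (149 and 15.4). Of 50 ribosome biogenesis genes 43 were lower (median -1.82), led by LYAR (70.1 and 4.84 FPKM), NLE1 (38.6 and 4.25) and MYBBP1A with a log2 ratio of -2.84. Nucleotide synthesis was lower in 21 of 22 members (median -1.88), among them PPAT (-2.63) and CAD (-2.48). The serine and one-carbon list was lower in 12 of 16 members, with MTHFD1L, PSAT1 and PHGDH at log2 ratios of -3.83, -3.77 and -3.37.

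Metabolic and cell cycle groups had medians below 0 in PBS as well. The nuclear genes of the electron transport chain and ATP synthase had a median of -0.90, with 21 of 47 members at least 2-fold lower, led by ATP5G1 (-3.03) and CYCS (-2.15). The TCA cycle list had a median of -0.85 and included PDHA1 (-1.85), MDH2 (-1.85) and FH (-1.81). In glycolysis 11 of 21 members were lower, such as the lactate transporter SLC16A1 (-2.68), GPI (-2.44) and LDHB (-2.34), while the glucose transporter SLC2A3 was higher (2.21). DNA replication and S phase genes were lower in 26 of 35 members (median -1.50), with RFC3 at -2.27 and MCM4 at -2.09, and G2 and M phase genes in 25 of 37 (median -1.15), with MAD2L1 at -2.66 and PLK1 at -2.20. Translation factors and tRNA synthetases had a median of -1.08 (VARS -2.43), lipid synthesis a median of -0.71 (SCD -3.11, FASN -2.58) and heat shock genes a median of -0.95. Ribosomal protein genes had a median of -0.38, at the 56.8th percentile of lists matched in expression. These highly expressed genes therefore did not stand apart from genes of like level, a pool that includes them.

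On the other side all 33 interferon response genes were at least 2-fold higher in the knockdown in PBS, with a median log2 ratio of 2.62. IFI27 rested on 15.7 FPKM in control and 183 FPKM in knockdown cells, EPSTI1 on 18.4 and 170.1 FPKM, and IFI6 on 116 and 957 FPKM. MHC class II genes were higher in 12 of 12 members (median 2.01), from the alpha chain HLA-DRA (912 and 3399 FPKM) to the trans-activator CIITA (31.1 and 129.5 FPKM). MHC class I genes were higher in 10 of 13 members (median 1.59), with HLA-E at 2.39. NF-kB and B cell activation genes were higher in 23 of 29 members (median 1.84), including the cytokine LTB (169 and 1383 FPKM), the chemokine CCL22 (143 and 1053 FPKM), TRAF1 (2.73) and the inhibitor TNFAIP3 (2.54). B cell identity genes were higher in 18 of 27 members (median 1.40), among them CXCR5 (2.48), FCRL1 (2.43) and CD72 (2.34). In the germinal centre list LMO2 was higher (2.68), with a list median of 0.21. The plasma cell list had a median of -0.45 (24.4th percentile), with 4 of 13 members lower, such as FKBP11 (-3.02) and SDC1 (-2.36), and 2 higher, TNFRSF13B (1.32) and CD27 (1.28). MYC-repressed targets had a median of 1.08, with TXNIP at 2.66 and BTG2 at 1.97.

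The lists closest to the study's question on chromatin differed from one another. The H3K4 methylation machinery had a median of 0.07 (-0.09 with the values as deposited; 66.7th percentile), with the core subunit WDR5 at -1.87 and the demethylases KDM1B at 1.53 and KDM5B at 1.10. The 2-oxoglutarate-dependent dioxygenases, which succinate can inhibit, had a median of 0.59 (99.5th percentile) with 19 of 24 members above 0, among them TET2 at 1.29, while EGLN3 was at -1.47. Replication-dependent histone genes had a median of 0.94, at percentile 99.97, and included HIST1H2AC (2.61). Of 12 myeloid markers 5 passed the filter and 4 of these were higher: ITGAM was 8.07 and 67.6 FPKM, LYZ 8.25 and 49.1 FPKM and CD68 9.27 and 58.6 FPKM, whereas AIF1 was at -0.37. The 4 T cell markers had a median of 0.35 (-0.13 with the values as deposited), from CD3E at -0.30 to CD2 at 0.86. Of the 3 epithelial and packaging-cell markers (median -1.67), TUBB3 was 273 and 24.6 FPKM, EPCAM 4.76 and 0.815 FPKM and VIM 436 and 1008 FPKM.

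The genes with the lowest ratios in PBS were SNHG9 and the neuropeptide gene GAL, both listed at 0 in the knockdown against 107 and 57.5 FPKM in control, MYC itself, the argininosuccinate synthase ASS1 (78.5 and 0.562 FPKM), NPW (41.3 and 0.275 FPKM) and HPDL (110 and 2.35 FPKM). SNHG9 overlaps another gene, and the log2 values of SNHG9 and GAL depend on the pseudocount. The highest ratios were those of IFI27, EPSTI1, LGALS3BP (23.8 and 212 FPKM), the joint row of IFI44 and IFI44L (19.2 and 171 FPKM), IFI6 and LTB. With the values as deposited the split became 1355 higher and 2225 lower, since that scaling moved the median of all genes by -0.14, and every list median named above kept its sign except those of the H3K4 machinery and the T cell markers.

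The same contrast in DMS asked what the Myc shRNA did when succinate was supplied, with MYC at 624 FPKM against 1649 FPKM in control. Interferon genes and myeloid markers stood further above control than in PBS, MHC, NF-kB and B cell identity genes less far above it, and growth genes less far below it: 1071 genes were at least 2-fold higher and 402 lower. Interferon genes were higher in 33 of 33 members with a median of 3.04, led by IFI27 (6.04, on 0.573 and 102 FPKM), the joint IFI44 and IFI44L row (4.40), IFI6 (4.03), SAMD9L (3.73) and IFIT1 (3.70). MHC class II genes were higher in 12 of 12 members (median 1.78), MHC class I in 9 of 13 (1.34), NF-kB genes in 21 of 29 (1.49, with LTB at 3.74 and the survival gene BCL2A1 at 3.13) and B cell identity genes in 18 of 27 (1.15). Myeloid markers had a median of 2.57, with ITGAM at 3.32.

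MYC-activated targets were at least 2-fold lower in 27 of 57 members in DMS, with a median of -0.99 against -2.17 in PBS, and MYC at 37.9% of control against 0.928%. Ribosome biogenesis was lower in 15 of 50 members (median -0.89), nucleotide synthesis in 10 of 22 (-0.99), DNA replication in 12 of 35 (-0.92) and G2 and M phase in 9 of 37 (-0.78). The lowest MYC-activated targets lay close together, with TERT at -1.38, SRM at -1.37 and PAICS at -1.30. MTHFD1L of the serine and one-carbon list was at -1.35, and SLC7A5 of the integrated stress response list was at -1.31. The lowest of the genes with a mean of at least 5 FPKM were IQCH-AS1 (-2.24), HIST1H2AL (-2.02), GALNT18 (-1.61), TEAD4 (-1.53), ALG14 (-1.49) and HIST1H2AJ (-1.48). With the values as deposited 911 genes were higher and 674 lower.

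The knockdown ratios of the 2 pairs of libraries, which share no library, had a Pearson correlation of 0.928 and a Spearman correlation of 0.961 across 11181 genes, which are not independent replicates. Of the 1663 genes higher in PBS, 1039 were higher in DMS too, where independent lists would share 159, and of the 1845 lower genes 395 were lower in DMS, where 66.3 would be shared. Large ratios were closer to their PBS size on the raised side than on the lowered side. In the 76 genes with a PBS ratio at or below -3 and a mean of at least 5 FPKM, the median was -3.44 in PBS and -1.25 in DMS (SD 0.17 across genes). In the 302 genes between -3 and -2 it was -2.32 in PBS and -1.06 in DMS. In the 220 genes above 2 it was 2.36 and 2.24.

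**Figure D2:**
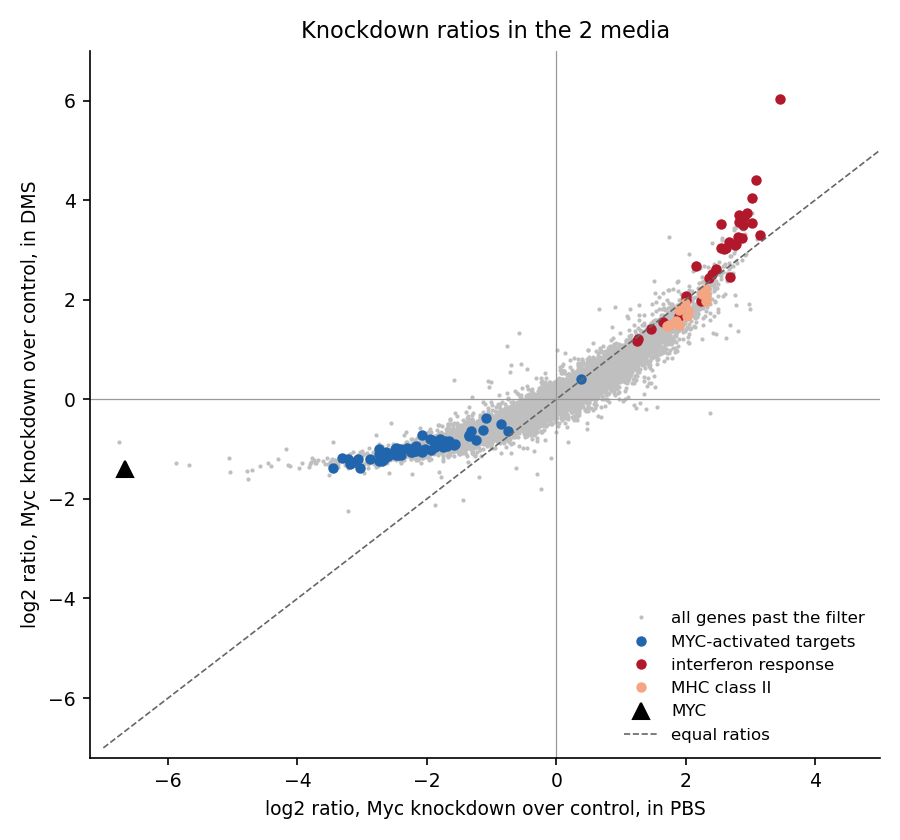
Log2 ratio of knockdown over control in DMS (y axis) against that in PBS (x axis), 1 point per gene, with 3 gene lists and MYC marked and a dashed line of equal ratios. Genes far below 0 in PBS level off in DMS, with a median of -1.25 for those at or below -3, while interferon genes lie near or above the dashed line.

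Over both media the limma fit tested the knockdown with medium as the second term. With Benjamini-Hochberg adjustment 3139 genes rose and 3074 fell, of 11181, and with no filter on low values 2951 rose and 1925 fell. In simulated data with 200 changed genes, 21.7% of this fit's calls were of unchanged genes, above the threshold. That share depends on how many genes change, so it does not measure the false calls among the genes given here. Among MYC-activated targets 56 of 57 fell and 0 rose; SRM fell by 2.41 on the log2 scale (SE 0.46, adjusted p = 0.00777 by limma) and was lower in both pairs. Ribosome biogenesis genes fell in 47 of 50 members, nucleotide synthesis in 22 of 22, DNA replication in 32 of 35, G2 and M phase in 34 of 37, the electron transport chain in 36 of 47 and the TCA cycle in 15 of 25. Of 60 ribosomal protein genes 26 fell and 1 rose. Interferon genes rose in 33 of 33 members, MHC class II in 12 of 12, MHC class I in 12 of 13, NF-kB genes in 26 of 29 (1 fell) and B cell identity genes in 22 of 27. Adjusted over the list alone, the counts were 39 of 47 for the electron transport chain, 33 of 35 for DNA replication, 13 of 13 for MHC class I and 23 of 27 for B cell identity, and the same as over all genes for the other lists just named, save 1 MYC-activated target that rose. A fit without the medium term called 2639 genes that rose and 2297 that fell. In that form of the fit, leaving out the control library in DMS as well gave 0 genes by limma (3541 at an unadjusted p under 0.05), and leaving out the control library in PBS gave 485 that rose and 4 that fell.

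The 10 genes that rose most were IFI27 (log2 fold change 4.75, SE 0.55, adjusted p = 0.00215 by limma), the joint IFI44 and IFI44L row (3.75), IFI6 (3.53), LTB (3.38), SAMD9L (3.34), IFIT2 (3.28), RSAD2 (3.28), ZBP1 (3.27), the lipid-presenting CD1C (3.27) and IFIT1 (3.27). Those that fell most were MYC (-4.04, SE 1.08, adjusted p = 0.0216 by limma), SNHG9 (-3.80) and GAL (-3.58), each listed at 0 in 1 library, ASS1 (-3.49), HPDL (-3.26), GALNT18 (-3.19), NPW (-3.11), the cystathionine synthase CBS (-3.11), KISS1R (-3.06) and DDN (-2.96). On the study axis SKP2 fell (-1.17, SE 0.21, adjusted p = 0.00711 by limma), as did SDHA (adjusted p = 0.00809 by limma), SDHB (-0.95), SDHD (-0.63), SDHAF1 (-0.59) and SDHAF3 (-1.31). SIRT3 (-0.32, adjusted p = 0.101 by limma), SDHC (-0.31, adjusted p = 0.168), SDHAF2 (0.29) and SDHAF4 (0.14) did not pass the threshold. Of the H3K4 machinery 5 of 20 members rose, among them KDM1B (1.29), and 6 fell, among them WDR5 (-1.40). Of 48 genes named by rule and called by limma, 32 kept the call with no filter, 30 kept the call without the medium term, 0 when the control library in DMS was also left out and 20 when that in PBS was.

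As groups the lists were tested over the same fit. By camera with a preset correlation 26 of 38 lists were called. The interferon list had an adjusted p of 1.61e-16 and the MYC-activated list 3.64e-13 by camera. These p-values take genes as nearly independent and do not measure the spread among libraries. With the correlation estimated from 1 residual degree of freedom no list was called (adjusted p = 0.594 or higher by camera). That form can hardly call a list, so it does not show that gene correlation removed the calls.

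The next comparison asked what DMS did in control cells, where MYC was 1856 FPKM in PBS and 1649 FPKM in DMS. Most immune genes lay below 0 and most antioxidant genes above 0, and few genes reached a 2-fold difference: 43 were at least 2-fold lower and 9 higher. NQO1, the quinone reductase and a target of the oxidative stress factor NRF2, had the highest ratio (12.1 FPKM in PBS, 27.2 in DMS). Other genes at the high end were the adenosine deaminase ADA (22.1 and 42.4 FPKM), the malic enzyme ME1 (log2 ratio 0.86), NGFRAP1 (8.14 and 15.4) and the transcription factor BHLHA15 (7.85 and 14.7). NRF2 targets had a median log2 ratio of 0.32, above all 10000 matched random lists, with 17 of 18 members above 0, of which only NQO1 was higher by 2-fold, and among them the haem oxygenase HMOX1 (0.60) and the ferritin chain FTH1 (0.57). Hypoxia and HIF targets had a median of 0.24 with 15 of 19 members above 0, led by PFKFB4 (0.77), while ANKRD37 (-0.65) and BHLHE40 (-0.49) were lower.

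Interferon genes were below 0 with DMS in 33 of 33 members in control cells, 9 of them by at least 2-fold (median -0.85), with IFI27 at 15.7 and 0.573 FPKM, IFI6 at 116 and 44.2 FPKM and IFIT1 at 10.9 and 3.76 FPKM. MHC class II genes were below 0 in 12 of 12 members, none by 2-fold (median -0.64, HLA-DRA -0.79), and NF-kB genes in 27 of 29, 4 of them by at least 2-fold (median -0.49). Among the latter CCL22 was 143 and 39.9 FPKM, LTB 169 and 48.7 FPKM and BCL2A1 12.2 and 4.20 FPKM. The other genes at the low end were HLA-DRB6 (10.4 and 1.28 FPKM), the chemokine CCL17 (37.2 and 7.94 FPKM) and CD1C (3.60 and 0.253 FPKM). B cell identity genes had a median of -0.32 (CXCR5 -0.83, MS4A1 -0.65) and myeloid markers one of -0.84. MYC-activated targets (-0.11), ribosome biogenesis (-0.11), DNA replication (-0.18) and G2 and M phase (-0.12) had medians slightly below 0, and the TCA cycle (-0.02), the electron transport chain (-0.01) and the H3K4 machinery (-0.08) lay near 0. With a pseudocount of 0.25 the counts were 104 lower and 34 higher, and with a minimum mean of 5 FPKM they were 37 lower and 1 higher (NQO1).

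The comparison at the centre of the design asked whether DMS raised expression in cells with depleted MYC. The 1845 genes lowered by the knockdown in PBS had a median DMS response of 0.74, short of 2-fold. MYC was among these genes, at 17.2 FPKM in PBS and 624 FPKM in DMS. Over all 11181 genes 535 were at least 2-fold higher and 58 lower. MYC-activated targets were higher in 31 of 57 members (median 1.05), among them NOP16 (17.4 and 71.5 FPKM), HSPD1 (54.7 and 214 FPKM), PAICS (15.4 and 60.8 FPKM) and SRM (26.8 and 104 FPKM). Ribosome biogenesis was higher in 16 of 50 members (median 0.89, LYAR at 4.84 and 21.7 FPKM), nucleotide synthesis in 7 of 22 (0.86, PAICS 1.91, PPAT 1.47) and serine and one-carbon metabolism in 7 of 16 (0.75, PSAT1 2.59, PHGDH 2.33). Medians were also above 0 for glycolysis (0.50, SLC16A1 1.68), the electron transport chain (0.39, ATP5G1 1.65) and the TCA cycle (0.38, MDH2 0.92), with SDHA at 0.46 and SDHB at 0.64. By at least 2-fold 6 of 21, 2 of 47 and 0 of 25 of their members were higher. The largest ratios belonged to SNHG9 and GAL, which were listed at 0 in PBS and stood at 44.8 and 20.4 FPKM in DMS, MYC (5.10), ASS1 (0.562 and 40.7 FPKM), CBS (0.0806 and 15.3 FPKM) and NPW (0.275 and 15.9 FPKM).

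Most immune genes lay below 0 with DMS in the knockdown cells as well. MHC class II genes were below 0 in 12 of 12 members (median -0.89, HLA-DPB1 -0.96), NF-kB genes in 27 of 29 (median -0.80, CCL22 -1.27, LTA -1.26, JUN -1.20), interferon genes in 33 of 33 (median -0.45, GBP1 -1.09) and B cell identity genes in 27 of 27 (median -0.52, CXCR5 -1.08). By at least 2-fold 5 NF-kB genes, 1 interferon gene, 1 B cell identity gene and no MHC class II gene were lower. Myeloid markers lay below 0 too, in 4 of 5 members (median -0.62). Genes raised by the knockdown also lie lower in a blend of the control DMS and knockdown PBS profiles, weighed below. These values alone therefore do not show a DMS response. The lowest ratios were those of the metallothionein MT1F (21.8 and 6.11 FPKM), the actin bundler FSCN1 (283 and 93.4 FPKM), HIST4H4 (11.9 and 3.43 FPKM), CCL17 (257 and 95.9 FPKM), NKAIN4 (28.1 and 10.0 FPKM) and GNG3 (log2 ratio -1.35). NRF2 targets had a median of 0.72, with NQO1 at 14.2 and 33.5 FPKM, TXN at 1.74 and SRXN1 at 1.59. Of 18 members 13 lay above 0, 6 of them by at least 2-fold, and 5 lay below 0. The H3K4 machinery had a median of -0.15, at percentile 6.63, with WDR5 at 0.87 and KDM1B at -0.81. With a minimum mean of 5 FPKM 36 genes were lower in place of 58, and with a pseudocount of 0.25 the number was 94.

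**Figure D3:**
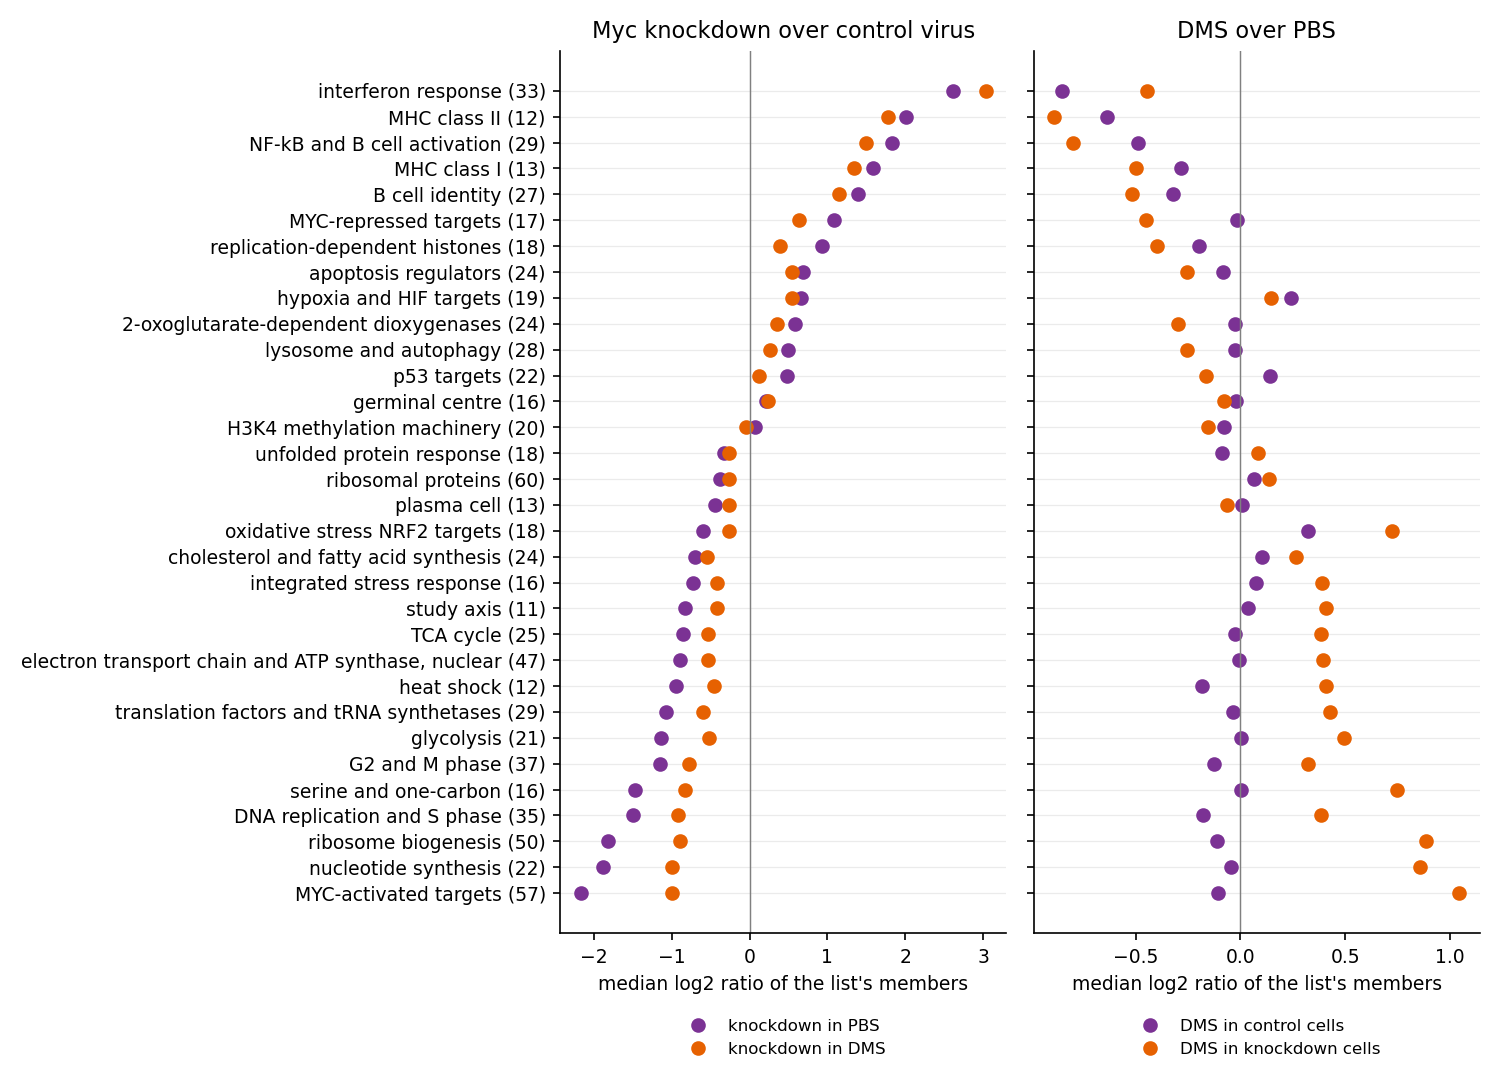
Median log2 ratio of each gene list with at least 10 members (number of members in brackets) for the knockdown in each medium (left) and for DMS in each cell population (right). With DMS, MYC-activated targets have medians of -0.11 in control cells and 1.05 in knockdown cells, whereas interferon, MHC class II and NF-kB lists lie below 0 in both.

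The DMS responses of the 2 cell populations, from pairs that share no library, had a Pearson correlation of 0.403 and a Spearman correlation of 0.413 across genes. Of the 43 genes lower in control cells 16 were lower in knockdown cells (0.223 expected of independent lists), and of the 9 higher genes 5 were higher (0.431 expected). The DMS response was at least 1 log2 unit higher in knockdown cells than in control cells for 499 genes and lower for 29 (10 with a minimum mean of 5 FPKM and 67 with a pseudocount of 0.25). For each gene this difference is also the knockdown ratio in DMS minus that in PBS, so it restates the shift in those ratios. Among lists with at least 10 members MYC-activated targets led this difference, with a median of 1.18 and 57 of 57 members above 0. Ribosome biogenesis (0.93), nucleotide synthesis (0.89) and serine metabolism (0.74) followed. The largest differences were those of SNHG9 (5.90), MYC (5.27), GAL (4.59), ASS1 (4.35), NPW (3.88) and HPDL (3.58), and the lowest those of HIST1H4E (-1.72), LINC01358 (-1.43), MRVI1-AS1 (-1.39), ALG14 (-1.19), MT1F (-1.19) and NKAIN4 (-1.17). A test of this difference was not possible, because 4 libraries leave no residual for an interaction.

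The return toward control was then measured in the genes that the knockdown had moved in PBS. The 1845 lowered genes had a median DMS response of 0.74 in knockdown cells and -0.01 in control cells, and 76.6% of them moved by at least 0.5 toward control. Because the genes were chosen on the same library, 100 simulations with no DMS effect were run, and their medians reached at most 0.0488, with 2.5% of genes moved on average. The 1663 raised genes had a median response of -0.49 in knockdown cells and -0.20 in control cells, with 46.6% moved against 2.97% in the simulations. Those returning most were SNHG9, MYC, ASS1, GAL, CBS and NPW on the lowered side, and MT1F, FSCN1, CCL17, NKAIN4, GNG3 and the complement regulator CFP (40.5 and 15.5 FPKM) on the raised side. Lowered genes chosen in the DMS pair instead (402) had medians of -1.12 in DMS and -2.35 in PBS.

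Over both viruses the limma fit called no gene for DMS with Benjamini-Hochberg adjustment (1429 genes at an unadjusted p under 0.05), and a fit without the virus term called none either (8 at an unadjusted p under 0.05). With the control library in PBS also left out of the latter fit, the knockdown library alone stood for PBS. Medium was then partly confounded with the knockdown, so no count from that fit is read as a response to DMS. Adjusted over the list alone, 25 of 33 interferon genes, 20 of 29 NF-kB genes, 12 of 12 MHC class II genes and 4 of 5 myeloid markers fell with DMS. Of 18 NRF2 targets 3 rose. By camera with a preset correlation 22 of 38 lists were called, the interferon (adjusted p = 1.90e-18), NF-kB (2.22e-15), MHC class II (2.42e-11) and B cell identity (1.66e-10) lists downward and the MYC-activated (1.31e-08) and NRF2 (4.06e-07) lists upward. None was called with an estimated correlation (adjusted p = 0.814 or higher by camera with an estimated correlation). As for the knockdown, that form has 1 degree of freedom and can hardly call a list. The p-values at the preset correlation take genes as nearly independent. The MYC-activated call averages opposite directions, since the list had a median of -0.11 in control cells, with 49 of 57 members below 0, and 1.05 in knockdown cells. The interferon call draws on both pairs. In knockdown cells, however, the interferon list was not lower than a blend of the control DMS and knockdown PBS profiles, weighed below, gives. Its median residual from that blend was 0.12, with 27 of 33 members above 0. For B cell identity genes and myeloid markers the median residuals were -0.09 (percentile 16.1 of matched random lists) and -0.05 (percentile 48.2). Those of the NF-kB and MHC class II lists were -0.27 and -0.33, below all matched random lists.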

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

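All tests of explanations in this part were chosen after the results were seen. Genes of which DMS moved the level in opposite directions in control and knockdown cells were singled out among the study axis, the top genes of each comparison, of the additive fit and of the return, where both responses were at least 0.25 in size (MYC was taken whatever its size); with 1 library per group, none of these differences was tested. MYC had a DMS response of -0.17 in control cells and 5.10 in knockdown cells, a difference of 5.27. For SNHG9 the responses were -0.38 and 5.52 (difference 5.90), and SNHG9 was listed at 0 in the knockdown in PBS. HIST1H2AJ had responses of -0.48 and 1.01 (difference 1.49). IQCH-AS1 had -0.33 and 0.65 (difference 0.97). The opposite order was seen for HIST1H4E (0.76 and -0.95, difference -1.72), LINC01358 (0.60 and -0.83, difference -1.43), MRVI1-AS1 (0.55 and -0.84, difference -1.39), ALG14 (0.62 and -0.57, difference -1.19) and HIST1H2AL (0.28 and -0.30, difference -0.57). Antisense and histone genes can share fragments with neighbours or relatives.

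A signal also lay outside the named genes. An unnamed row on chromosome 14 from 106725316 to 107170240 (hg19), inside the immunoglobulin heavy chain locus, stood at 106961 FPKM in the control in PBS and 223308 FPKM in the knockdown in PBS, a log2 ratio of 1.06. It was 90015 FPKM in the control in DMS and 174487 FPKM in the knockdown in DMS.

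The first pattern weighed is that genes lowered by the knockdown in PBS stood closer to control in the knockdown library in DMS. Selection on the shared library is argued against, since the median return of 0.74 lies above the highest simulated median of 0.0488. A return that shrinks every log2 ratio by 1 common factor is argued against too. It left a median residual of 0.90 in the 76 genes at or below -3. A mixed sample, in which a fixed share of cells or RNA has the control profile, predicts that ratios level off whatever their depth, and the slope of the DMS ratio on the PBS ratio in those genes was 0.0178 (bootstrap 95% interval -0.0439 to 0.0970). Blending 37.9% of the control DMS profile with the knockdown PBS profile left a root mean square error of 0.151 on the log2 scale. The model of 1 common log2 factor left 0.286, but its residual also carries the spread of the control PBS library. These errors are therefore not like for like. Incomplete infection or loss of knockdown in part of the cells, or carry-over of control RNA, may account for the pattern. A return of every cell by 1 common share of its FPKM distance to control gives the same blend and cannot be told apart. DMS acting on these genes in cells that all stayed low in MYC is argued against as the whole cause, since MYC was 36.3-fold higher in the same library, while DMS raising MYC itself cannot be told apart from a mixed sample, because MYC regained 37.2% of its distance to the control in DMS and a blend gives that level too.

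The second pattern is that most immune genes lay below 0 with DMS in control cells. By at least 2-fold 9 of 33 interferon, 4 of 29 NF-kB and 0 of 12 MHC class II genes were lower. Knockdown cells or RNA in the control PBS library would give this if their share were 8.90%, the median that the 74 genes of the interferon, NF-kB and MHC class II lists need (quartiles 7.28% and 10.2%). As the whole cause this predicts that the 76 genes at or below -3 are higher in DMS by 0.13. Their median response was 0.0123 (SE 0.0343 across genes). These genes were chosen on the same control PBS library, which pulls their response down, and the size of that pull was not simulated. The SE treats genes as replicates and leaves out error in scaling. The gap therefore does not settle whether a mixed sample was the whole cause. A mixed sample together with a further DMS effect on the lowered genes cannot be told apart from a DMS effect alone, since the 8.90% is read from the pattern's own genes and no other control library bears on it. A DMS response present in knockdown cells too is consistent with the NF-kB and MHC class II genes, whose median residual beyond the blend was -0.29, below all matched random lists, and stays open for interferon genes, whose residual was 0.12, above all of them, but whose response in knockdown cells was -0.45 without assuming a blend.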

How the results depend on the processing

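Counts, correlations, list medians, list calls, named genes and the median return were recomputed with 1 choice changed at a time. Fits with a library left out also lacked the second term. The pair overlaps, the residuals beyond the blend, the slope and the share read from the immune genes were not recomputed. The causes of the changes were not tested unless stated. Scaling by the median ratio kept the count of each single comparison and of the additive fit within 1.5 times. As deposited, 674 genes in place of 402 were lower with the knockdown in DMS. With a minimum mean of 5 FPKM, which tests fewer genes, 1 gene in place of 9 was higher with DMS in control cells, 36 in place of 58 were lower with DMS in knockdown cells, and 10 in place of 29 had a lower DMS response in knockdown cells. With a pseudocount of 0.25, an added choice that widens ratios of low genes by construction, these were 34, 94 and 67, and 104 in place of 43 genes were lower with DMS in control cells (138 in place of 52 in either direction). With no filter 1925 genes in place of 3074 fell with the knockdown in the additive fit.

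Without the second term the fit called 4936 genes for the knockdown in place of 6213. Leaving out 1 library from that fit gave 0 to 7310 genes for the knockdown (0 to 3632 rose, 0 to 3678 fell), the lowest without the control library in DMS. For DMS it gave 0 to 38 genes, all of which rose. The highest DMS count came from the fit without the control library in PBS, in which the knockdown library alone stood for PBS. Medium was then partly confounded with the knockdown, so that count is not read as a response to DMS. With a library left out, the lone library of an arm is assumed to vary like the others. The spread comes only from the 2 libraries of the other arm, so it includes any difference between those 2. Of 48 named genes called for the knockdown, 32 kept the call with no filter, 30 without the second term, 0 without the control library in DMS, 20 without that in PBS, 41 without the knockdown in PBS and 47 without the knockdown in DMS. The additive value of HIST4H4 (0.58) ranged from -0.19 without the knockdown library in PBS to 1.35 without that in DMS. The correlation of the knockdown ratios was 0.916 with no filter, 0.934 with a minimum mean of 5 FPKM, 0.912 with a pseudocount of 0.25 and 0.910 with small RNA genes kept, against 0.928. That of the DMS ratios was 0.373 with no filter and 0.329 with small RNA genes kept, against 0.403. Camera with an estimated correlation called 0 lists in place of 26 for the knockdown and 0 in place of 22 for DMS. With 1 degree of freedom that form can hardly call a list, so the change says nothing about gene correlation. The median return of lowered genes ranged from 0.68 to 0.78. The count-based tests, exact intervals and binomial splitting were not run because the values are not counts. Replicates could not be paired because each group has 1 library. The additive fit did match libraries by medium for the knockdown and by virus for DMS. The limits that depth sets could not be computed without counts.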

Other observations

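The tests of hypotheses below were chosen after the results were seen, except that of NRF2 targets, whose prediction was written before its value. Further lists are given here for the knockdown in PBS, with percentiles among matched random lists. Apoptosis regulators had a median log2 ratio of 0.69 (99.9th percentile), with the survival genes BCL2A1 (2.41), BIRC3 (2.37) and BCL2 (1.90) and the death gene HRK (2.21) all higher. The p53 list had a median of 0.48 (percentile 98.3), with FAS at 1.93 and TP53INP1 at 1.99. Lysosome and autophagy genes had a median of 0.49 (percentile 99.2), among them the cathepsin CTSZ (1.82) and the lysosomal regulator TFEB (1.42). Hypoxia and HIF targets had a median of 0.65 (percentile 99.3), with BHLHE40 at 1.74 higher and MXI1, also a MYC network member, at -1.67 lower. The integrated stress response list had a median of -0.73 (percentile 2.59), with amino acid genes such as SLC7A5 (-3.81) and PSAT1 (-3.77) lowest. The unfolded protein response list (-0.33, 39.4th percentile, MANF -1.83) and the MYC network factors (0.18, 72.9th percentile, MXD4 0.95) did not stand apart from matched lists. Nor did the 5 nuclear non-coding RNAs (-0.08, 59.8th percentile), of which MALAT1 (8.34 and 27.8 FPKM) and NEAT1 (4.97 and 19.1 FPKM) were higher and the joint row of SNHG1 (84.1 and 40.7 FPKM) was lower. The fibroblast and endothelial list had 3 members past the filter, of which COL1A1 was 0.915 and 8.96 FPKM.

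A hypothesis is that DMS raised NRF2 targets in both cell populations, as an electrophilic or oxidative stress could. A mixed sample alone predicts that the list has no residual beyond the blend of 37.9% control DMS and the rest knockdown PBS. Its median residual was 0.11, above all 10000 matched random lists, with 17 of 18 members above 0, so the blend alone is argued against for this list. Random lists do not keep the correlation among a list's genes, so such a rank is reached more easily. Glycolysis reached it too, with a median residual of 0.06. NQO1 had a residual of 0.78. Part of the knockdown response of genes such as TXN follows the blend, and the control DMS library enters both values, so the hypothesis rests on 1 library per group.

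Of other lists some departed from the blend in the same direction as their DMS response in control cells and some did not. Hypoxia and HIF targets had a median residual of 0.18 (17 of 19 members above 0) and a response of 0.24 in control cells. DNA replication and S phase genes had a residual of -0.25 with 0 of 35 members above 0 and a response of -0.18 in control cells, and G2 and M phase genes had -0.20 with 0 of 37 above 0 and -0.12. The residual did not follow for p53 targets (-0.09 at percentile 12.4, with a response of 0.14 in control cells) or for cholesterol and fatty acid synthesis (-0.10 at percentile 11.6, with a response of 0.10), and interferon genes went the opposite way (0.12 and -0.85). Glycolysis had a residual of 0.06, with 14 of 21 members above 0, and a response of 0.002 in control cells. The medians of matched random lists were between -0.06 and -0.03 for the hypoxia, S phase and G2 and M phase lists. Among genes with a mean of at least 5 FPKM, and chosen after their values were seen, the highest residuals were those of COL24A1 (1.15), LINC00378 (1.10) and ANKRD37 (0.87), and the lowest those of HIST1H2AL (-1.20), IQCH-AS1 (-1.13) and MT1F (-1.09).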
